A study of Streptococcus gordonii str. Challis with 8 samples.

How the data were processed

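RNA from 8 samples of the *S. gordonii* arcR knockout, 4 with and 4 without arginine in the final medium, was labelled with Cy3 and hybridised to 1 Agilent array per sample. Per the labels' protocols, cultures grown in defined medium with 0.5 mM arginine were split, collected, resuspended in fresh medium of either kind and held for 30 min at 37 °C before RNA was stabilised. Labelled RNA was made from 50 ng of RNA, per the labels. The series' design text names biological replicates.

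Spots were measured with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The deposited scanner files hold spot intensity on a linear scale, which Feature Extraction had corrected for background and detrended within each array, per the file headers; no scaling between arrays is recorded there. The deposited value table holds log2 values, 1 per probe, and how the authors made it is not given in the sources used here. Its scale and centring were found by setting each column against the scanner values. Slopes of 0.938 to 0.993 on differences between arrays showed a log2 scale. Each column correlated at r = 0.90 to 0.97 with its best matching scan, whose log2 signals had been centred on each probe's median. The values of the table were therefore taken as centred per probe. Column medians were -0.031, -0.024, 0.010 and -0.046 for arginine replicates 1 to 4 and 0.012, 0.0055, 0.079 and 0.046 for the no-arginine replicates. The direction was settled by these positive slopes, while the exact centring and the scaling between arrays stay unknown. Columns were joined to probes by probe name.

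Of the 12830 spots of an array, 12294 were not controls and covered 2049 probes. Probe names give a first and last base and a strand on the RefSeq chromosome of this strain (1064 on the plus and 985 on the minus strand, up to position 2196625). All of these lengths are multiples of 3, from 72 to 10941 bp with a median of 777, so they are coding lengths, and 1 joined name is shortened in the files. Neighbours overlap in 364 pairs, and a probe's share of such an overlap is not known here. The files pair no probe with a gene name. The gene lists fixed in advance, among them arginine catabolism and synthesis, were therefore not analysed here, nor was the signal of arcR.

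For each probe, the log2 processed signal was averaged over its spots, without the 1.72% to 2.52% of spots that Feature Extraction had marked as outliers, and the array's 75th percentile was subtracted. No spot was saturated. A coding sequence was tested if over 50% of its spots were well above background on all 4 arrays of at least 1 medium. This kept 1984 and left out 65, of which 28 were well above background on no array, and 1919 were above it on all 8. Signals were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Each change is the no-arginine mean minus the arginine mean. A sequence not well above background on any array of a medium has only a bound there. It was computed as the brighter medium's mean over the dim medium's mean of, per array, the higher of the lowest signal among probes above background and the sequence's own.

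The sequences named individually were the 12 with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap. This rule, the comparison and most alternatives were set before the data were examined. Runs were defined after the changes had been seen, as at least 4 neighbouring sequences on a strand, all past the threshold in the same direction, and were described where the mean log2 change was at least 2 in size. Median SD between replicates was 0.37 log2 units without and 0.27 with arginine. The p-values measure the spread between these samples.

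The procedure was tested on simulated data for this comparison, with 1984 sequences and changes of known size in 50 of them per size. It recovered 8% of changes of 0.5 log2 units, 72% of changes of 1 and 100% of changes of 2 and of 4. Among 1784 unchanged sequences it made 11 calls. The simulated noise was independent between sequences and arrays, whereas the real arginine arrays of a slide deviated together. A far smaller share of sequences was changed than the 50.8% called in the data. These figures therefore need not hold for the real comparison.

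Arrays lay on 2 slides, each scanned in 1 session, with replicates 1 and 2 of both media on slide 1 and replicates 3 and 4 on slide 2. Alternatives covered normexp background correction (offset 50), quantile, median and spike-in scaling, the filter on dim probes, outlier marks, eBayes with trend and robust options, the replicate and slide as blocks, each slide alone, each array left out, stricter thresholds and the authors' value table. Normexp with this offset adds 50 units to each corrected signal, which makes changes of dim sequences smaller. It was added after the data had been seen and used the median spot signals because the scanner files hold no column of mean signals. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were made with matplotlib 3.10.9.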

Results

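Transcript levels were measured in *Streptococcus gordonii* strain Challis, an oral commensal bacterium, carrying a deletion of arcR, which encodes a transcriptional regulator of the ArgR/AhrC type. The question addressed was which transcripts of this knockout respond to arginine. Cells growing in defined medium with arginine were moved for 30 min at 37 °C to fresh medium with 0.5 mM L-arginine or with none, and RNA from 4 biological replicates of each medium was hybridised to 8 single-channel arrays. Each array carried 1 probe for each of 2049 coding sequences, printed as 6 spots per probe. The 75th percentile of spot signal ran from 3548 to 7290 intensity units between arrays, and 94.3% to 98.4% of the spots of an array were well above background. Normalized signals correlated across coding sequences at r = 0.925 to 0.992 within a medium and at 0.819 to 0.902 between media, and no arrays were identical. The number of arrays limits the precision.

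The files name probes by their position and strand on the RefSeq chromosome and pair none with a gene name, so coding sequences are given here by their first and last base. The signal of arcR itself was not analysed here, and both groups carry the deletion, so the labels were not checked through that gene. Groups were taken from the scanner file recorded for each sample. In the deposited table of processed values, 4 of the 8 columns followed the scanner file of another sample: the columns of arginine replicates 3 and 4 followed the scans of no-arginine replicates 1 and 2, and the reverse. Each direction given here rests on the scanner files. With the table's columns taken as labelled, limma called 0 sequences (230 at an unadjusted p under 0.05). With each column given to the array it followed, it called 1025.

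**Figure D1:**
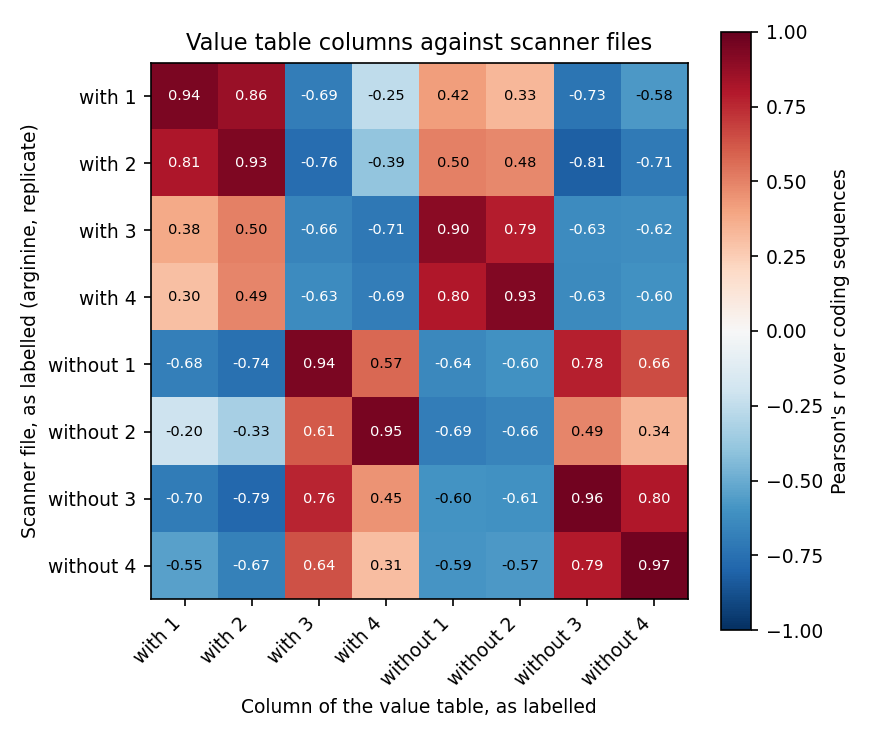
Pearson's r over coding sequences between each column of the deposited value table (horizontal axis) and the row-centred log2 signal of each scanner file (vertical axis), both as labelled by medium and replicate. The columns of arginine replicates 3 and 4 and of no-arginine replicates 1 and 2 have r between -0.64 and -0.69 with their own scan and between 0.90 and 0.95 with a scan of the other medium.

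Without arginine the signal of 1007 of 1984 tested coding sequences (50.8%) changed. Of these, 473 were higher and 534 lower without arginine, by limma with Benjamini-Hochberg adjusted p under 0.05. The largest rises lay in 4 neighbouring coding sequences at 1618239 to 1622366 on the minus strand, which rose 317-fold to 422-fold, or 142-fold to 216-fold with normexp background correction in place of the processed signal. The largest fall was 33.2-fold at 1635586 to 1635825 on the minus strand (22.5-fold with normexp). Large changes came in groups of neighbours: of the 12 largest rises and the 12 largest falls, 22 belonged to runs of at least 4 neighbours on a strand that moved in the same direction. A 2-fold change or more was reached by 640 of the called sequences (270 higher, 370 lower), and an 8-fold change by 31 in each direction. All 4 values of a medium lay outside those of the other medium for 947 sequences (47.7%, against 2.86% by chance).

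**Figure D2:**
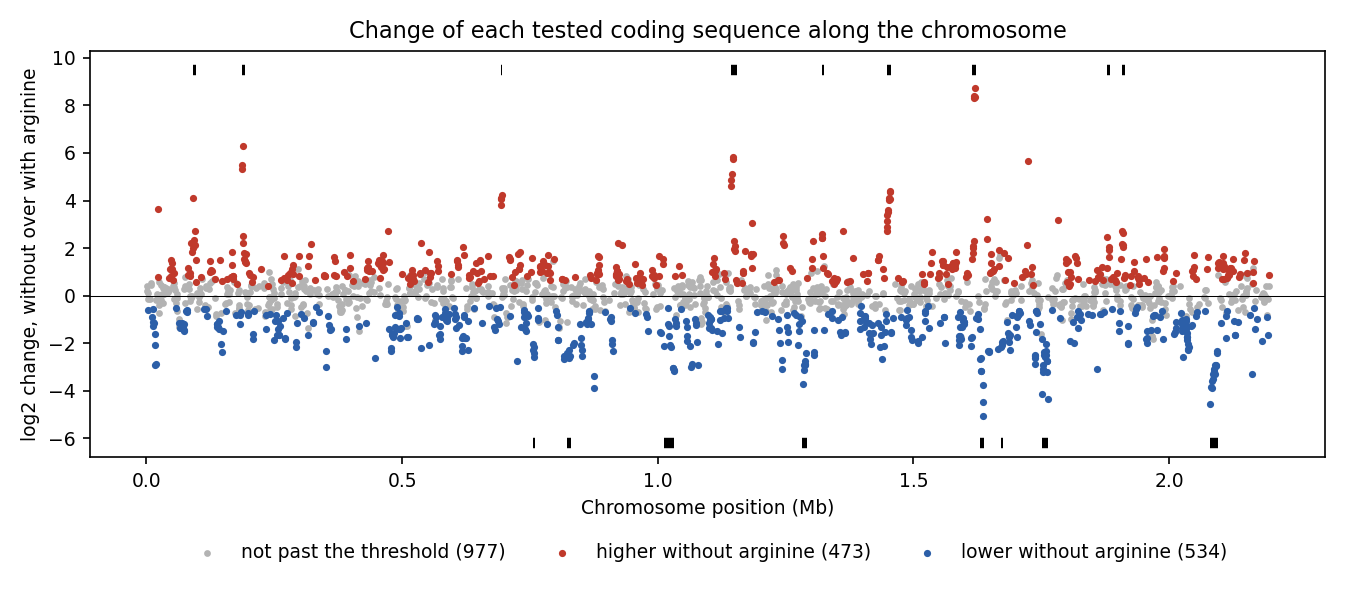
Log2 change of each of the 1984 tested coding sequences, without over with arginine (vertical axis), at its chromosome position in Mb (horizontal axis). Red points are the 473 higher and blue points the 534 lower sequences past the threshold, grey points are the others, and black bars mark the 9 described runs that rose (top) and the 9 that fell (bottom); the highest points, at 8.31 to 8.72, lie near 1.62 Mb.

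The balance of rises and falls depended on how the arrays were scaled. With arrays scaled to the added spike-in RNAs in place of the 75th percentile, 559 sequences passed, 160 higher and 399 lower, so that rises were 28.6% of the calls against 47.0%. The majority turned with median scaling (584 higher, 464 lower, 55.7% rises) and with quantile normalization (532 higher, 499 lower, 51.6%). The median change moved from -0.0022 to -0.18 log2 units with spike-in scaling and to 0.13 with median scaling.

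The steepest rise was at 1615354 to 1622366 (minus strand), where 9 coding sequences rose by a mean of 4.84 log2 units (28.6-fold). Mean normalized log2 signal over this run was 1.17 ± 0.27 without arginine and -3.67 ± 0.18 with it (SD, n = 4 arrays each). Within it, the sequence at 1621344 to 1622366 (probe CUST_1524_PI428083087) rose by 8.72 ± 0.24 log2 units (SE), 422-fold, with a limma adjusted p of 1.91e-08. It was well above background on 3 of the 4 arginine arrays, and with normexp its rise was 142-fold, the smallest of the 4. Its neighbours at 1618239, 1619384 and 1620133 rose 317-fold, 342-fold and 327-fold (214-fold, 144-fold and 216-fold with normexp). The other 5 members, at 1615354 to 1617758, rose by 1.55 to 2.31 log2 units, so the change was uneven along the run.

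A second run with an uneven rise was found on the plus strand at 186069 to 192723, with 8 coding sequences and a mean of 3.32 log2 units. Its first 3 members rose by 5.51, 5.32 and 6.28 log2 units, the last of these being a sequence of 96 bp at 188724 to 188819 (77.7-fold). The 5 that followed rose by 1.43 to 2.50. Run means were 2.54 ± 0.16 without and -0.79 ± 0.06 with arginine, and no-arginine replicate 4, at 2.29, lay below the other 3 arrays of its medium. A similar step was seen in the plus-strand run at 1142924 to 1154561, where the first 5 of 10 sequences rose by 4.60 to 5.83 log2 units and the others by 0.68 to 2.28. The sequence at 1147682 to 1147972 rose 57.0-fold (33.9-fold with normexp) and that at 1144355 to 1147534, 3180 bp long, 35.2-fold.

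On the minus strand, 11 coding sequences at 1447747 to 1456054 rose by 2.70 to 4.38 log2 units (mean 3.66, 12.6-fold), from a run mean of -4.27 ± 0.52 to -0.62 ± 0.45. The 4 at 692644 to 695382 rose by 3.83 to 4.21 (mean 4.05, 16.5-fold), and for 3 of them the rise was 3.04 to 3.25 within slide 1 and 4.86 to 5.28 within slide 2. Near 0.09 Mb, 4 plus-strand sequences at 91144 to 96431 rose by a mean of 2.83. Of these, the sequence at 93748 to 94485 was not well above background on any arginine array, so its rise was at least 2.34-fold, and the run mean was 2.55 with that bound and 1.88 with normexp. Smaller mean rises were measured at 1908101 to 1913589 (4.19-fold, 6 sequences) and at 1320929 to 1324400 (4.15-fold, 5 sequences). At 1879430 to 1884856 the mean rise of 4 sequences was 4.05-fold, but it came to 0.68 log2 units within slide 1 and 3.36 within slide 2. Outside these runs, the minus-strand sequence at 1723341 to 1724987 rose by 5.65 ± 0.20 log2 units (SE; 50.2-fold, limma adjusted p = 9.73e-08), from -1.57 ± 0.15 to 4.08 ± 0.34 (SD, n = 4).

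**Figure D3:**
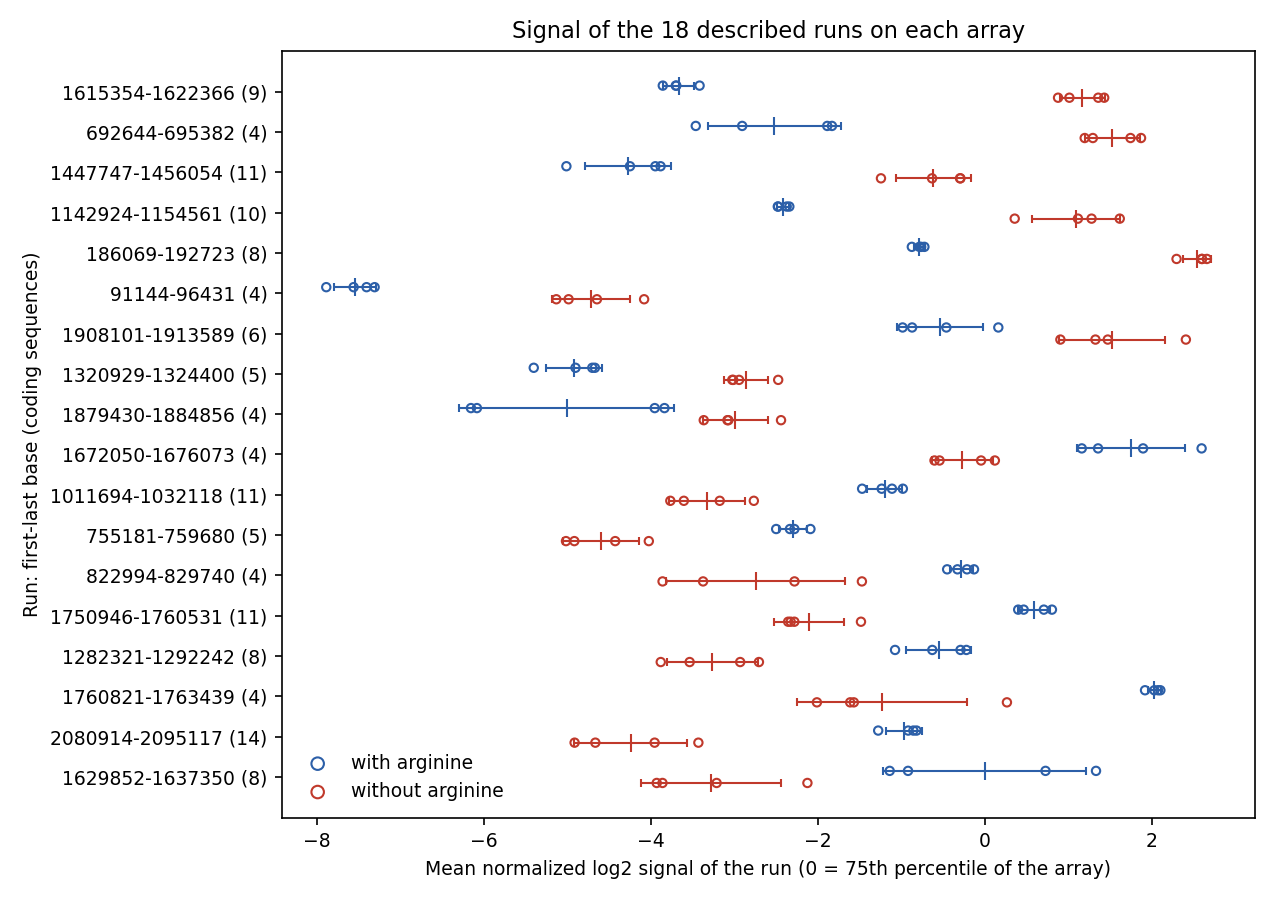
Mean normalized log2 signal of each of the 18 described runs (horizontal axis, 0 is the 75th percentile of the array) on each array, by run with its first and last base and number of coding sequences (vertical axis). Circles are the 4 arrays of a medium, with arginine in blue and without in red, ticks are group means and bars the SD; the run at 1615354 lies at 1.17 without and -3.67 with arginine.

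The 9 described runs that fell held 4 to 14 coding sequences. The longest of them, at 2080914 to 2095117 (minus strand), held 14 coding sequences that fell by a mean of 3.27 log2 units (9.67-fold), from -0.97 ± 0.21 with arginine to -4.24 ± 0.68 without (SD, n = 4). Its sequence at 2080914 to 2082323 (probe CUST_1940_PI428083087) fell by 4.58 ± 0.42 log2 units (SE, limma adjusted p = 6.94e-05) and was well above background on 1 of the 4 no-arginine arrays. Its fall was 23.9-fold, but 2.85-fold with normexp, so its size depends on how background was handled. The neighbours at 2082334 and 2083400 fell 14.5-fold and 14.8-fold (4.97-fold and 12.6-fold with normexp), and the log2 changes at 2084125 and 2085444 were -3.58 and -3.50 (3.32-fold and 8.23-fold with normexp). Within slides 1 and 2 the falls were 9.42-fold and 23.2-fold at 2083400, and 7.22-fold and 19.9-fold at 2084125. The run mean was -2.59 within slide 1, -3.95 within slide 2 and -2.65 with normexp.

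The 8 minus-strand sequences at 1629852 to 1637350 fell by a mean of 3.28 log2 units (9.72-fold), with a wide spread between arrays (-0.0015 ± 1.22 with and -3.28 ± 0.84 without arginine). Its sequence at 1635586 to 1635825 (probe CUST_1536_PI428083087) fell by 5.05 ± 0.68 log2 units (SE, limma adjusted p = 4.15e-04), and those at 1635161 and 1635917 fell 22.4-fold (35.5-fold without no-arginine replicate 2) and 13.4-fold (8.71-fold with normexp). A pair of runs that fell lay close together on the minus strand, with a coding sequence between them that belonged to neither. At 1750946 to 1760531, 11 sequences fell by a mean of 2.70 (6.52-fold), with no-arginine replicate 4 at -1.48 above the other 3 arrays of its medium, and at 1760821 to 1763439, 4 sequences fell by 3.26 (9.60-fold). The largest changes in this pair were at 1762648 to 1763439 (20.6-fold) and 1751739 to 1752395 (17.3-fold).

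Other falls of this kind were found at 1282321 to 1292242 (8 sequences, 6.54-fold), at 822994 to 829740 (4 sequences, 5.52-fold), at 755181 to 759680 (5 sequences, 4.91-fold), at 1011694 to 1032118 (11 sequences, 4.37-fold) and at 1672050 to 1676073 (4 sequences, 4.05-fold). In the run at 1282321, the sequence at 1283517 to 1285967 fell 13.2-fold (7.56-fold within slide 1 and 23.0-fold within slide 2), but 3.54-fold with normexp, and was well above background on 3 of the 4 no-arginine arrays. Mean changes were -1.97 within slide 1 and -3.45 within slide 2 for the run at 1282321, and -1.70 and -3.23 for that at 822994. Outside the runs, the plus-strand sequence at 875683 to 876027 fell 14.7-fold (limma adjusted p = 1.23e-04).

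Runs of at least 4 neighbours that changed in the same direction numbered 74 in all, 31 higher and 43 lower, and held 448 of the 1007 called sequences. When the calls were shuffled over the tested sequences, such runs held 32.1 sequences on average and 82 at most (permutation p = 1e-04, one-sided, the smallest that 10000 shuffles can give). The longest run, at 2023988 to 2032915, held 17 sequences that were lower by a mean log2 change of -1.30. A further 260 called sequences had no adjacent sequence on their strand that was called in the same direction.

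Within slide 1, which held replicates 1 and 2 of both media, limma called 674 sequences (302 higher, 372 lower), and within slide 2, with replicates 3 and 4, 1117 (532 higher, 585 lower). With the slide as a block the count was 1194 (575 higher, 619 lower). Of the 568 sequences called within each slide alone, 562 had the same direction on both, and the log2 changes of the slides correlated across coding sequences at r = 0.842, with sequences not being independent replicates. The change differed between slides for 54 sequences by limma's interaction test, of which 38 changed in the same direction on both slides and more on slide 2, and 11 had opposite signs. This count rests on few arrays: it was 9 with spike-in scaling and, without arginine replicate 3, 0 by limma (246 at an unadjusted p under 0.05). On each slide 1 row of arrays held the arginine samples and the other the no-arginine samples, so array row and medium cannot be told apart.

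**Figure D4:**
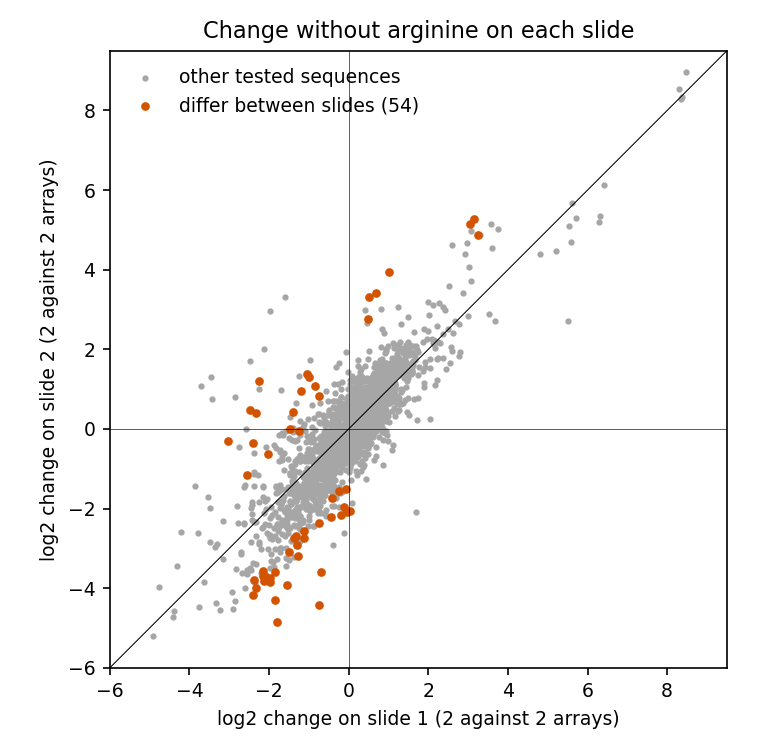
Log2 change without over with arginine of each tested coding sequence on slide 1 (horizontal axis) and on slide 2 (vertical axis), each from 2 against 2 arrays; the line marks equal change. Orange points are the 54 sequences whose change differed between slides by limma's interaction test; r over all tested sequences was 0.842.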

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

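Of the tests reported here, the interaction between medium and slide, the test on neighbouring sequences, the test of background noise and the correlation of deviations between slides were chosen only after the results they bear on had been seen.

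A sample far from the others of its medium was found in 7 of 96 groups of 4 arrays examined, where chance gives about 1 in 20. The groups are not independent, since named sequences are also members of runs. In 4 of the 7 the sample was no-arginine replicate 4. Its normalized log2 signal for the sequence at 187283 to 188668 was 4.58 against 4.93 to 4.98 in the other 3 arrays. Its mean for the run at 186069, which holds that sequence, was 2.29 against 2.60 to 2.66. For the run at 1320929 its mean was -2.48 against -3.03 to -2.94, and for the run at 1750946 it was -1.48 against -2.36 to -2.28. Its value lay nearer to the arginine arrays than those of the other replicates, except for the run at 1320929, where it lay farther from them.

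The array of arginine replicate 3 stood apart in 3 measures of its background. On it 94.3% of spots were well above background against 97.4% to 97.7% on the other arginine arrays, and the SD of its negative control spots was 4.40 intensity units against 1.18 to 1.67. The lowest signal it rated well above background was 5.27 on the log2 scale against 3.63 to 3.80. Without this array 874 sequences passed the threshold, 398 higher and 476 lower.

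The change differed between the slides for 54 coding sequences (limma interaction, adjusted p under 0.05; 394 at an unadjusted p under 0.05), 53 of which were well above background on all arrays. All 4 members of the run at 1879430 to 1884856 were among them, with log2 changes of 0.49 to 1.03 on slide 1 and 2.76 to 3.93 on slide 2. So were 3 neighbours at 1083497 to 1084672, with changes of -0.19 to 0.03 on slide 1 and -2.16 to -2.05 on slide 2. With arrays scaled to the spike-in RNAs, 9 sequences passed this test. Without arginine replicate 3, 0 passed (limma, 7 arrays; 246 at an unadjusted p under 0.05), although all 54 kept the sign and at least 50% of the size of their difference, which their selection on all 8 arrays favours.

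Noise of single probes is argued against for these 54 as a set, since 29 had a same-strand neighbour among them that differed in the same direction, against 1.63 on average and 10 at most in random sets (permutation p = 1e-04, the smallest that 10000 sets can give). The noisier background of arginine replicate 3 is argued against as well: adding or removing 3 SDs of its negative controls (13.2 intensity units) left all 54 with at least 50% of their difference, their median signal on that array being 7261 units. Different cultures or handling behind the slides may account for the pattern, because the arginine arrays of the separate slides deviated from their medium's mean in opposite ways (mean r = -0.80 across sequences), a value that centring on the mean of 4 arrays pushes below 0 in any case. The no-arginine arrays gave a mean r of -0.54 between slides. Within a slide the deviations correlated at 0.65 and 0.56 in the arginine arrays but at 0.09 and 0.19 in the no-arginine arrays. Cultures and slides cannot be told apart with 2 arrays of each medium per slide, and no biological explanation was tested.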

How the results depend on the processing

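Normexp on median signals, the value table matched to arrays and the described runs were chosen after seeing the data; the other alternatives were planned. In 21 settings that take groups from the scanner files, all 501 values of the individually named sequences kept their direction and stayed past the threshold, and none of 371 run means reversed, while 25 moved by over 1 SD. Normexp moved the fold of 9 named sequences and 2 runs by over 1.5 times, down to 2.85-fold at 2080914; its offset shrinks dim signals' changes. Each slide alone moved 3 named sequences and 5 runs by as much.

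The count of 1007 sequences lay between 959 and 1057 with normexp (1020), quantile (1031) or median scaling (1048), with other dim-probe filters or outlier handling, and with the replicate number as a block (1057; 505 higher, 552 lower). Same-numbered samples deviated together at r of -0.34, 0.53, 0.45 and 0.11, and the best partner carried the same number for 2 of the 4, so the numbers were not taken as pairing. The block changed the call of no individually named sequence. Leaving out each array gave 852 to 1097 sequences, 395 to 534 higher and 457 to 563 lower. Spike-in scaling gave 559, with 160 higher. All 640 sequences called with an absolute change of 1 or more kept their sign, and 518 of them were still called. The offset between spike-in RNAs and 75th percentile had an SD between arrays of 0.46 log2 units without and 0.47 with arginine. The median SD of a sequence was 0.37 and 0.27. The cause of the lower count was not tested. Slide 1 alone gave 302 higher and slide 2 alone 532; the cause was not tested. Stricter thresholds (adjusted p under 0.01, 311 higher; absolute change of 1 or more, 640 with 270 higher) lowered counts by construction.

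The value table as labelled gave 0 sequences, 0 higher and 0 lower (limma; 230 at an unadjusted p under 0.05), and only there did signs reverse. Log2 changes became -0.54 at 1618239, -0.17 at 188724, -0.25 at 1147682, -0.051 at 1148039, -0.21 at 1723341, -0.23 at 1144355, -0.22 at 1143255, 0.98 at 875683 and 0.59 at 1762648. Run means became -0.32 at 692644, -0.14 at 1447747, -0.30 at 1142924, -0.29 at 91144, -0.22 at 1908101, -0.75 at 1879430, 0.39 at 1750946 and 0.61 at 1760821. By its construction this setting exchanges 2 arrays of each medium.

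Probe summaries, a probe-level test and handling of saturated spots were not run, with 1 probe per sequence and no saturated spot, nor normexp on mean signals or the gene lists. Signal over background limits levels below it, as in the 65 sequences not tested.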

Other observations

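The comparisons of neighbours, sequence lengths and chromosome windows, both tests on the value table and those of array brightness and of the scaling were chosen only after the results had been seen.

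Short and long coding sequences differed in direction. Of the 497 shortest tested sequences (72 to 507 bp) 30.2% were higher and 25.8% lower without arginine, and of the 493 longest (1197 to 10941 bp) 17.2% were higher and 31.4% lower. The difference was 12.9 percentage points for rises (permutation p = 1e-04, the smallest that 10000 draws can give) and -5.69 points for falls (p = 0.043), both two-sided and unadjusted, from draws that treat neighbours as independent. By position, the share of lower sequences in 11 windows of 200000 bp ran from 19.7% at 1800001 to 2000000 to 40.4% in the adjoining window at 2000001 to 2200000, a range that was not tested.

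Neighbours that lie close together may share transcripts, a hypothesis drawn from these data. Log2 changes of same-strand neighbours that overlapped or lay under 50 bp apart correlated across 825 pairs at r = 0.944 (rho 0.918). The r was 0.632 from 50 to below 200 bp, 0.240 at larger distances and 0.122 for 329 pairs on opposite strands. The median difference within a pair was 0.21 and 0.80 log2 units for the closest and the opposite-strand pairs (permutation p = 1e-04, the smallest possible). Pairs are not independent, a probe within an overlap may detect both sequences, and transcript ends were not measured.

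That 1007 sequences changed, 50.8% of those tested, was weighed against chance, array position and scaling. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many calls, the real one, and the highest other count was 3. This argues against chance but cannot exclude it, since 1 in 35 is the smallest share that these splits can give. A single brightness factor per array row could not make these calls, because subtracting each array's 75th percentile had already removed it. Without any scaling between arrays 178 were higher and 667 lower, which therefore adds nothing on this point. Row effects that differ between sequences were not tested. The 75th percentile scaling is argued against as the whole cause, since a scale factor moves all sequences of an array one way and spike-in scaling left 160 higher and 399 lower, although the balance of directions and the total did depend on it. The medium, which the design names, stays as the open explanation, and it coincides with array row.

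The exchange of columns in the value table was weighed between its likely sources. All 8 columns followed the scanner file that has the same place when files are sorted by slide and position, in line with columns filled in slide order. Scanner files linked to the wrong samples could give the same exchange, and the media would then be the separate slides. That source would have the table's own labels separate the media, but with them 0 sequences passed (limma, 230 at an unadjusted p under 0.05). The 1007 calls would then lie between array rows within a medium. These counts cannot decide between the sources. The difference between rows would enter the spread within each medium and could hide changes between media. No split other than that by the scanner files gave more than 3 calls. Wrongly linked scanner files are therefore not excluded, and no probe was tied to a gene with a known response. No biological explanation was tested.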
